A study of Homo sapiens with 12 samples.

How the data were processed

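RNA from 3 sublines of 22Rv1 cells was hybridised to 12 Illumina HumanHT-12 v4 bead arrays. Each subline carried a doxycycline-inducible hairpin, scrambled or 1 of 2 against HNF4G, and was grown in RPMI medium with 10% serum without doxycycline or with it for 3 days. Per the labels, RNA was purified with RNeasy columns and 500 ng were labelled with biotin. The groups were 6 groups of 2 arrays, taken from the sample labels, which number the replicates and say no more about them.

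The deposited non-normalized table gives the intensity of 47323 probes in each array, in the scanner's units, and beside it the detection p-value that the authors' software (BeadStudio, version not given in the sources used here) computed from the negative control beads, in steps of 1 in 770. In the deposited series matrix the values are log2 intensities that the authors normalized with Partek (version not given), and each array has the same median of 6.67. The analysis started from the non-normalized table, from which 1479 blank lines were left out. Median intensity was 92.5 to 108 per array and the lowest intensity 70.7 to 80.2. Within a group the 2 arrays correlated at 0.989 to 0.991 across genes, and their difference had a standard deviation of 0.27 to 0.31 log2 units.

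In R 4.3.3 with limma 3.58.1 and statmod 1.5.0, neqc corrected the background with normexp by the detection p-values, added an offset of 16, and applied quantile normalization and log2. Probes were kept with a detection p under 0.01 on at least 2 arrays, which left 19172. Of all probes, 30113 had 1 gene symbol in the annotation, 8 had several and 17202 were not listed, and 30074 were matched by gene ID to the reference, which changed 0 symbols. Of the kept probes 14767 had a gene name and 4405 had no single gene name and were left out of the tests of genes. For each gene the probe with the highest mean over all arrays was used (2899 genes had more than 1 kept probe), so that 11164 genes were tested. A linear model over the 6 groups with empirical Bayes moderation (6 residual and 7.91 prior degrees of freedom, median residual SD 0.18) gave 9 contrasts: doxycycline against none in each subline, the mean hairpin response, and each hairpin response, minus the scrambled response, the difference of the hairpin responses, and each hairpin subline against the scrambled subline without doxycycline. The p-values of genes are from limma, two-sided, adjusted by Benjamini and Hochberg over the genes, with a threshold of 0.05. Second probes and probes without a single gene name were tested in another fit, over all 19172 kept probes, and adjusted over those probes.

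The 20 gene lists, the contrasts and the rule for naming genes were fixed before the data were examined. Lists covered gastrointestinal transcription factors, intestinal and gastric epithelium, hepatic secreted proteins, glucuronidation and steroid metabolism, androgen activated and androgen repressed genes, the cell cycle, p53 targets, the interferon response, the amino acid and integrated stress response, mitochondrial ribosome and respiratory chain, cholesterol synthesis, hypoxia and glycolysis, the unfolded protein response and heat shock, cytosolic ribosomal proteins, and markers of luminal prostate epithelium, basal epithelium, neuroendocrine cells, fibroblasts and stroma, and blood and immune cells. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. The text names HNF4G, its paralog HNF4A, SPINK1 and 3 control genes in the comparisons (1 further gene of the rule is not reported here); the 12 largest mean falls and rises among genes shared by the hairpins; the 12 largest falls and rises past the threshold in the main test; the 5 largest each way in every other contrast; and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, the 5 smallest p are named. Other list members that passed, and second probes, were named after their values were seen.

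Where a probe was not detected on both arrays of a group, the change is given as a bound. It is the brighter group's mean intensity against the dim group's mean of, in each array, the higher of the lowest signal among detected probes and the probe's own signal. No fold is given where both groups were below background. Genes shared by comparisons that use the same control arrays were set beside lists drawn independently and beside simulated groups with nothing changed.

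The pipeline was tested on simulated data of 11164 genes with 200 changed genes, in 20 simulations. At a log2 change of 1 it recovered 92.6% of the changed genes with hairpin 1, 70.1% in the main test and 46.3% for hairpin 1 against the scrambled response, and at 0.5 it recovered 12.9% and 4.48% in the first 2. A list of 25 genes shifted by 0.5 was found in 20 of 20 simulations, and an unshifted list in 0. The simulated genes varied independently, so this gives no error rate for lists whose members vary together. The adjustment is stricter where fewer genes change, and the main test called 30 genes in the data. The share recovered in the main test may therefore be too high for these data.

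The alternatives tried were no background correction, scaling to the median, the series matrix values, no filter, a filter on all 12 arrays, the replicate number as a block, only the arrays of each comparison, array weights, a trended and robust prior, every probe tested, a 1.5-fold minimum, and leaving out each array in turn. A slide block was not run because the table names no slide. Genes without a probe that passed the filter, among them KLK3, were not analysed here.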

Results

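RNA levels across the human transcriptome were measured on 12 Illumina bead arrays in 22Rv1 cells, a line derived from a human prostate carcinoma. Each of 3 sublines carried a short hairpin RNA that is switched on by doxycycline: a scrambled control hairpin, or hairpin 1 or hairpin 2 against HNF4G, a nuclear receptor of the hepatocyte nuclear factor 4 family. Each subline was sampled without doxycycline and after 3 days of doxycycline, so that there were 6 groups of 2 arrays. The median intensity per array ran from 92.5 to 108 and the mean intensity from 278 to 407. Of 47323 probes, 14959 to 18293 per array were above background. Scrambled, doxycycline, replicate 1 was the dimmest array (median intensity 92.5, 14959 probes detected), and the other 11 arrays had medians of 97.2 to 108 and 15783 to 18293 detected probes. The number of arrays, 2 per group, limits the precision of every value. The labels do not say whether the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Changes are given as log2 differences ± the standard error from limma (2 arrays per group), with p-values adjusted over the 11164 genes tested. Those of second probes were adjusted over the 19172 kept probes.

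HNF4G itself was examined in every array before any other gene. Without doxycycline its normalized log2 intensity was 6.35 and 6.13 in the scrambled subline, 6.30 and 6.18 in the hairpin 1 subline and 6.40 and 6.49 in the hairpin 2 subline. With doxycycline it was 5.81 and 6.19 in the scrambled subline, 4.73 and 4.83 in the hairpin 1 subline and 4.71 and 4.35 in the hairpin 2 subline. None of the 4 doxycycline arrays with an HNF4G hairpin had HNF4G above background (detection p 0.0935, 0.0468, 0.0961 and 0.727). HNF4G fell with hairpin 1 (-1.46 ± 0.18, adjusted p = 8.01e-04), which amounts to at least 2.08-fold lower. With hairpin 2 it fell too (-1.92 ± 0.18, adjusted p = 8.50e-05), at least 2.48-fold lower. In the scrambled subline its change of -0.24 ± 0.18 did not pass the test (adjusted p = 0.699). The mean hairpin response was below the scrambled response (-1.45 ± 0.22, adjusted p = 0.00803), a call that was lost without scrambled, no doxycycline, replicate 2 (adjusted p = 0.0701). Without doxycycline HNF4G differed from the scrambled subline by 0.01 ± 0.18 in the hairpin 1 subline and by 0.21 ± 0.18 in the hairpin 2 subline. Neither difference passed. The control genes ACTB (actin), GAPDH (a glycolytic enzyme) and B2M (the light chain of HLA class I) had changes of 0.16, -0.23 and 0.10 with hairpin 1. With hairpin 2 they were -0.23, -0.20 and 0.49, and none of these changes passed. HNF4A, which was chosen beforehand with HNF4G, had no probe of its own name among the genes tested and was not analysed here.

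**Figure D1:**
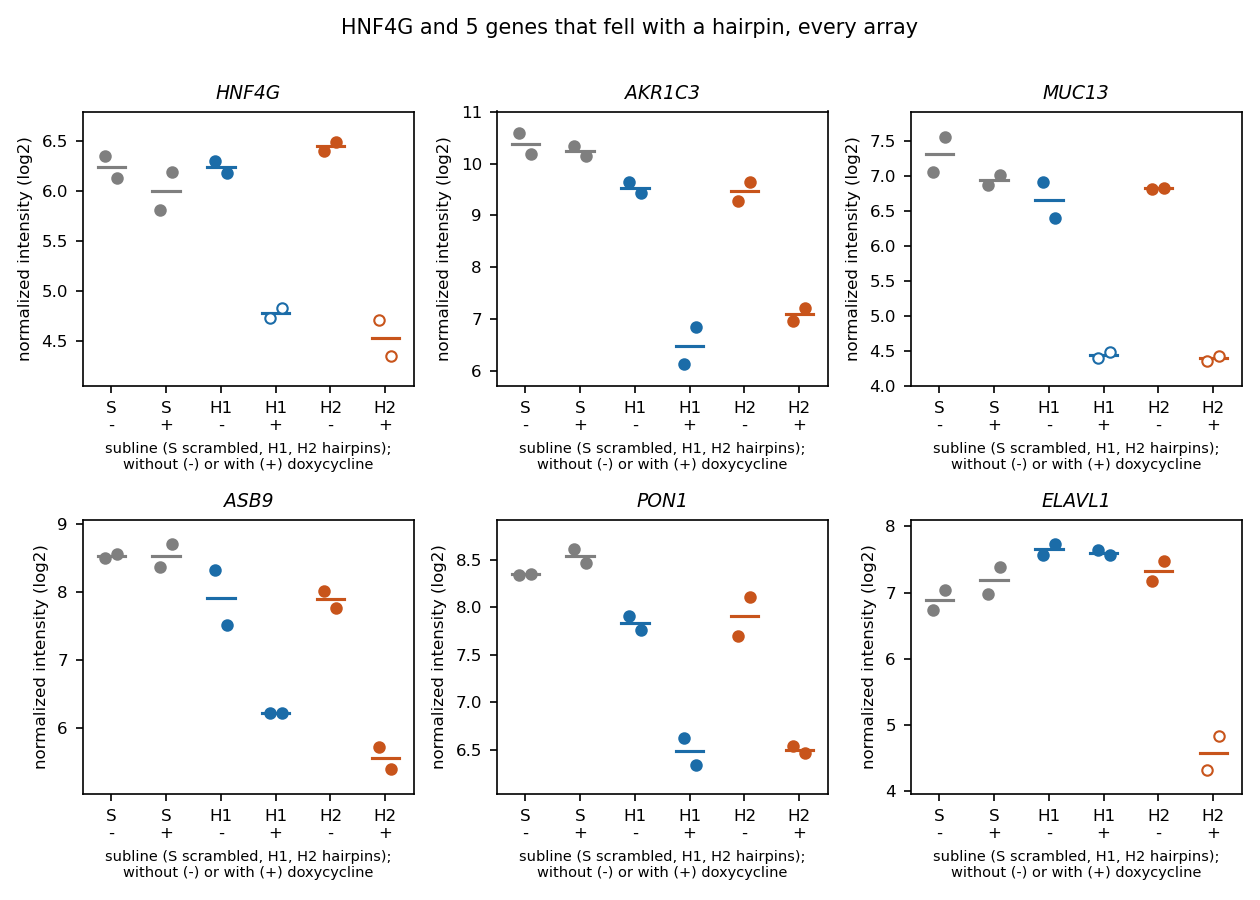
Normalized log2 intensity of HNF4G and of 5 genes named in the report, for every array. Points are arrays (2 per group), horizontal lines are group means, and open points were not above background. HNF4G lay between 4.35 and 4.83 in the 4 doxycycline arrays with an HNF4G hairpin and between 5.81 and 6.49 in the other 8 arrays, and ELAVL1 fell with hairpin 2 (log2 -2.75) and changed by -0.05 with hairpin 1.

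What both hairpins shared was asked of the genes that passed in each hairpin subline. AKR1C3, which makes testosterone from androstenedione, fell most on the mean of both hairpins (-3.05 ± 0.23, adjusted p = 3.29e-05 with hairpin 1 and -2.37 ± 0.23, adjusted p = 1.02e-04 with hairpin 2, against -0.15 ± 0.23 in the scrambled subline). MUC13, a transmembrane mucin of the gut lining, dropped below background with both (-2.22 ± 0.20, adjusted p = 4.19e-05, at least 2.77-fold, and -2.43 ± 0.20, adjusted p = 2.57e-05, at least 3.23-fold). The brush-border myosin MYO1A did so too (-1.76 ± 0.14, at least 2.12-fold, and -1.83 ± 0.14, at least 2.21-fold). A1CF, the cofactor of apolipoprotein B messenger RNA editing, dropped below background with hairpin 1 (-1.90 ± 0.21, at least 3.10-fold). With hairpin 2 A1CF was detected on 1 of 2 arrays (-1.73 ± 0.21). The liver product ALB (albumin) fell with both (-1.69 ± 0.14 and -1.34 ± 0.14). So did the lipoprotein-bound esterase PON1 (-1.35 ± 0.17 and -1.41 ± 0.17) and the ubiquitin ligase adaptor ASB9 (-1.69 ± 0.23 and -2.34 ± 0.23).

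In all, 47 genes changed the same way with both hairpins, 41 down and 6 up. From 93 and 159 genes that fell and 25 and 72 that rose, independent lists would share 1.32 and 0.161 genes (Fisher's exact test across genes, p = 1.85e-52 and 9.36e-09, where genes are not independent replicates). TMED5, a protein of vesicle transport, and the zinc finger gene ZNF585A were the 2 genes that passed in opposite directions (-0.69 and -0.77 with hairpin 1, 0.80 and 0.71 with hairpin 2). A second ZNF585A probe, near background, changed by -0.08 and -0.46 and did not pass. The other falls among the 12 largest were AKR1C4 (-2.19 and -1.70) and AKR1C2 (-1.59 and -1.86), which reduce steroids. AKR1C2 changed by -1.17 in the scrambled subline (adjusted p = 0.0513) and did not pass against it (-0.55 ± 0.23, adjusted p = 0.351). NFASC, an adhesion protein, fell as well (-1.27 and -1.78, detected on 1 of 2 arrays with hairpin 1 and at least 2.39-fold lower with hairpin 2), although a second, dimmer NFASC probe changed by 0.08 and 0.03 and did not pass. So did the brush-border protein BAIAP2L2 (-1.15 and -1.62) and HNF4G. The 3 AKR1C genes are close paralogs, so the share of each probe's signal that belongs to its own gene is uncertain. Of the 6 genes that rose, 3 were TNFRSF19, a receptor of the tumour necrosis factor family (1.20 and 0.90), the ectoenzyme gene ENPP5 (0.85 and 1.08), and RCBTB2 (1.05 and 0.80). The others were the cilium gene CFAP69 (0.97 and 0.86), the noncoding RNA LINC00623 (0.83 and 0.97) and the fibronectin receptor subunit ITGA5 (0.72 and 1.03, with the hairpin 1 group without doxycycline detected on 1 of 2 arrays). Across all genes the responses to the hairpins correlated with Pearson r = 0.23 and Spearman rho = 0.15. Each hairpin correlated with the scrambled response at r = 0.06 and 0.03. Genes are not independent replicates. Leaving out 1 array of the hairpin 2 subline lowered the 47 genes to 22 and 22 (no doxycycline, replicates 1 and 2) or to 17 and 20 (doxycycline). Leaving out 1 of the hairpin 1 subline lowered them to 30 (no doxycycline, replicate 2) or to 25 and 26 (doxycycline). With hairpin 1 the rise of ITGA5 was kept in 0 of the 12 such fits and that of ENPP5 in 1, and with hairpin 2 those of TNFRSF19 and RCBTB2 in 2.

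**Figure D2:**
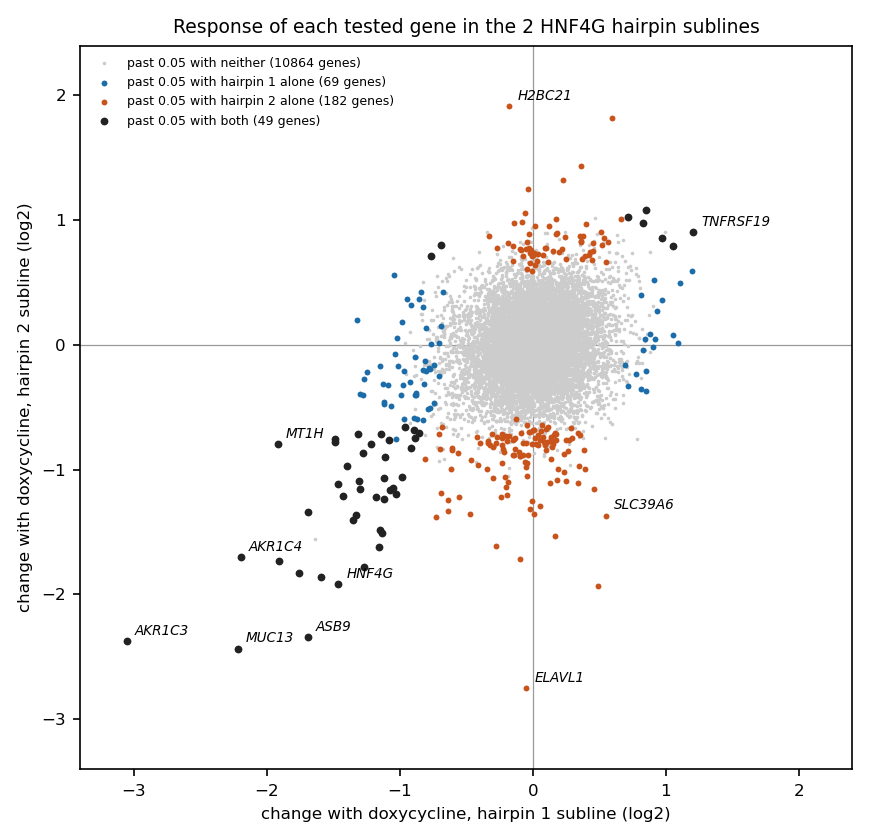
Log2 change with doxycycline of the 11164 tested genes in the hairpin 1 subline (x axis) and the hairpin 2 subline (y axis). Dark points passed with both hairpins (49 genes, of which 47 changed the same way), coloured points with 1 of them; AKR1C3, MUC13 and ASB9 lie far down on both axes, and ELAVL1 on the hairpin 2 axis.

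The main test set the mean response of both hairpins against the scrambled response, which removes what doxycycline and the induction of a hairpin do in the control subline. Among the largest falls beyond the control were those of AKR1C3 (-2.57 ± 0.28, adjusted p = 0.00363), ASB9 (-2.03 ± 0.28, adjusted p = 0.00663), MUC13 (-1.96 ± 0.24, adjusted p = 0.00430), NFASC (-1.79 ± 0.23, adjusted p = 0.00430), PON1 (-1.57 ± 0.21, adjusted p = 0.00556) and AKR1C4 (-1.56 ± 0.23, adjusted p = 0.00750). ELAVL1, which encodes the RNA-stabilising protein HuR, fell by this test too (-1.70 ± 0.25, adjusted p = 0.00749). This value rests on hairpin 2 (-2.75) and not on hairpin 1 (-0.05). The metallothionein genes MT1F (-1.47 ± 0.21) and MT1H (-1.41 ± 0.21), whose products bind zinc and copper and whose sequences are near-identical, A1CF (-1.45 ± 0.26) and the small Cajal body RNA SCARNA23 (-1.54 ± 0.25) complete the 12 largest falls with HNF4G. SCARNA23 was below background in 3 of the 6 groups. Second probes of ASB9 (-1.18), A1CF (-1.42) and NFASC (0.40) did not pass in this test, and those of PON1 (-1.37, adjusted p = 0.0180) and ALB (-1.35, adjusted p = 0.0138) did.

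Of 30 genes past the threshold, 26 fell against the control and 4 rose, and 20 of the 30 belonged to the 47 genes shared by the hairpins. The 4 rises were ANKRD52, a subunit of protein phosphatase 6 (1.94 ± 0.23, adjusted p = 0.00430), the phospholipid phosphatase relative PLPPR2 (1.67 ± 0.24, adjusted p = 0.00749), the microtubule-end protein MAPRE3 (1.48 ± 0.21, adjusted p = 0.00745) and GALNT1, which starts mucin-type glycosylation (1.20 ± 0.18, adjusted p = 0.00869). Their mean changes over the hairpin sublines were 0.13, 0.32, 0.24 and 0.29, none past the threshold with either hairpin. Their changes in the scrambled subline were -1.81, -1.34, -1.24 and -0.91. Taken alone, the hairpin 1 response differed from the scrambled response for 35 genes (27 lower, 8 higher), led by AKR1C3 (-2.91), MT1H (-1.97), SCARNA23 (-1.86), MUC13 (-1.85) and MT1F (-1.82) on the low side. On the high side were ANKRD52 (1.95), MAPRE3 (1.67), PLPPR2 (1.58), the MAP kinase phosphatase gene DUSP8 (1.58) and C21orf91 (1.44). The count of 35 fell to 21 and 9 (no doxycycline, replicates 1 and 2) or 6 and 11 (doxycycline) without a scrambled array and to 9 and 17 or 4 and 2 without a hairpin 1 array. It was 20 without either hairpin 2 doxycycline array. Of these 10 calls AKR1C3 and MT1H were kept in all 12 such fits, MT1F in 11, ANKRD52 in 10, MAPRE3 in 8, MUC13, SCARNA23 and C21orf91 in 7, DUSP8 in 6 and PLPPR2 in 3. The hairpin 2 response differed for 36 genes (28 lower, 8 higher), led by ELAVL1 (-3.05), ASB9 (-2.35), AKR1C3 (-2.23), MUC13 (-2.07) and NFASC (-2.04). Higher were ANKRD52 (1.93), the histone genes H2AC6 (1.80) and H2BC21 (1.76), PLPPR2 (1.75) and TMLHE, an enzyme of carnitine synthesis (1.36). The count of 36 fell to 10 without scrambled, no doxycycline, replicate 2, and without a hairpin 2 array to 14 and 10 (no doxycycline) or 5 and 9 (doxycycline). ELAVL1 and NFASC kept their calls in all 12 fits, ASB9, MUC13 and ANKRD52 in 11, AKR1C3 in 9, H2BC21 in 7, H2AC6 and PLPPR2 in 6 and TMLHE in 5. HNF4G passed against the control with hairpin 2 (-1.68 ± 0.25, adjusted p = 0.0112) and missed the threshold with hairpin 1 (-1.23 ± 0.25, adjusted p = 0.0664). The hairpin 2 call was lost without scrambled, no doxycycline, replicate 2, and without replicate 2 of either hairpin 2 group. SPINK1, a secreted trypsin inhibitor that was chosen beforehand, differed from the control by -0.68 ± 0.23 (adjusted p = 0.245) and did not pass.

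The 2 comparisons against the scrambled response use the same control arrays. They shared 7 lower and 4 higher genes where independent lists would share 0.0677 and 0.00573 and simulated unchanged groups shared 0. The simulation called 0 genes in either comparison, so its overlap of 0 was fixed in advance. The covariance of the 2 comparisons across genes was 0.0758 against 0.0370 in the simulation (r = 0.53 against 0.50). Each part of a divided control group would hold 1 array, so the controls were not split, and part of the excess may come from the shared controls. A change in the scrambled subline itself would also enter both comparisons. ANKRD52 and PLPPR2, higher in both, fell there (-1.81 and -1.34). With every array scaled to the same median, the median change of all genes in the main test moved from 0.01 to 0.26 and the split from 4 up and 26 down to 43 up and 13 down of 56 genes. That scaling matched the median of all 47323 probes, of which 14959 to 18293 per array were above background, and not that of the tested genes. The changes here are therefore relative to the all-gene median that quantile scaling holds near 0. The same scaling gave 31 higher and 6 lower for hairpin 1 alone (all-gene median 0.32) and 12 and 12 for hairpin 2 (0.19). Without background correction 52 rose and 73 fell. The count of 30 fell to 15 without scrambled, no doxycycline, replicate 2 and to 14 without scrambled, doxycycline, replicate 1. ALB (-0.93 ± 0.18, adjusted p = 0.0457) lost its call at the probe used here whichever of the 12 arrays was left out. A1CF kept its call in 5 of 12 such fits, BAIAP2L2 in 7 and UGT2B15 in 2. Without scrambled, doxycycline, replicate 1 the calls of AKR1C4, MT1F, SCARNA23 and PLPPR2 were lost, without scrambled, no doxycycline, replicate 2 those of MT1F, SCARNA23 and MAPRE3, and without replicate 1 of that group that of GALNT1.

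Among the 20 gene lists fixed beforehand, 3 were shifted down in the main test. Of 25 measured genes of intestinal and gastric epithelium, 4 fell and 21 did not pass (camera, adjusted p = 0.0121; median -0.08, mean -0.29; adjusted over the list alone, 6 fell): MUC13, A1CF, MYO1A and BAIAP2L2 (-1.09). Of 25 genes of glucuronidation and steroid metabolism, 3 fell and 22 did not pass (adjusted p = 0.0121; median -0.11; adjusted over the list alone, 5 fell): AKR1C3, AKR1C4 and UGT2B15, which glucuronidates androgens (-1.20). None of 72 cell cycle genes passed alone (median -0.13), and the list as a whole was lower (adjusted p = 0.0256; 0 adjusted over the list alone). All 3 calls were lost with an estimated correlation, where the adjusted p was 0.113 for the intestinal list, 0.113 for glucuronidation and 0.165 for the cell cycle. All 3 were lost without scrambled, no doxycycline, replicate 2 (adjusted p = 0.0530 for each). Against the scrambled response, hairpin 1 alone lowered the intestinal list (adjusted p = 0.00227), glucuronidation (0.0382), p53 targets (0.0382) and the integrated stress response (0.0478). Hairpin 2 alone lowered glucuronidation (0.0126) and the cell cycle (0.0126) and raised the interferon list (0.0134). Each of these calls was lost, the lowest with adjusted p = 0.0919 with an estimated correlation. For hepatic secreted proteins 1 of 14 fell (ALB; adjusted p = 0.0686), and for the 11 measured gastrointestinal transcription factors none passed (adjusted p = 0.871). The other lists did not pass in this test: androgen activated genes (adjusted p = 0.473), androgen repressed genes (0.799, with a median of 0.20 against a mean of -0.08) and p53 targets (0.393). The same holds for interferon response (0.160), amino acid and integrated stress response (0.160), mitochondrial ribosome and respiratory chain (0.473), cholesterol synthesis (0.473), hypoxia and glycolysis (0.160), unfolded protein response and heat shock (0.930) and cytosolic ribosomal proteins (0.930, median -0.03 and mean 0.01). Markers of luminal prostate epithelium (0.393), basal epithelium (2 genes, 0.393), neuroendocrine cells (0.522), fibroblasts and stroma (0.160) and blood and immune cells (0.740) did not pass either.

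**Figure D3:**
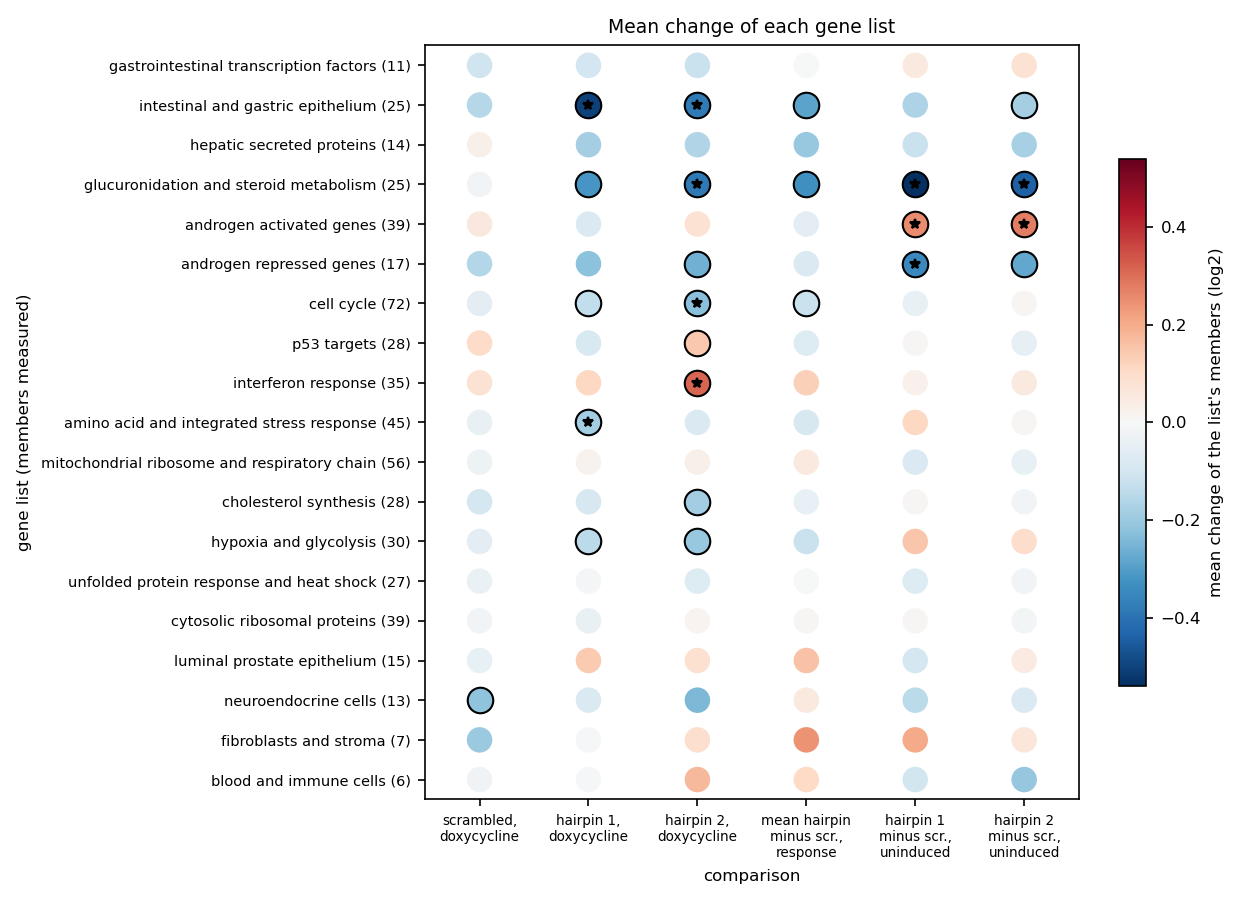
Mean log2 change of the measured members of 19 of the 20 gene lists (rows, with the number measured) in 6 comparisons (columns); the basal list with 2 genes is left out. Colour gives the mean change, a black ring marks an adjusted p under 0.05 by camera with the preset correlation and a star a call that holds with an estimated correlation. The intestinal list passed with a star for hairpin 1 and hairpin 2 and with a ring alone in the test against the scrambled response.

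Doxycycline in the scrambled subline served as the control for the drug and for an induced hairpin, although 1 subline cannot tell their effects from other differences between its arrays. Here 3 genes passed, and all fell: ANKRD52 (-1.81 ± 0.19, adjusted p = 0.00177) and PLPPR2 (-1.34 ± 0.20, adjusted p = 0.0312), both detected on 1 of 2 doxycycline arrays, and MAPRE3 (-1.24 ± 0.17, adjusted p = 0.0255), at least 2.28-fold lower. AKR1C2 (-1.17 ± 0.19, adjusted p = 0.0513) and GALNT1 (-0.91 ± 0.15, adjusted p = 0.0513) had the next smallest p-values and did not pass. By limma 1076 genes had an unadjusted p under 0.05, against 1378 with hairpin 1 and 1720 with hairpin 2. Each of these counts is above 0.05 of the 11164 genes, the share that unchanged genes would give. The 3 calls therefore do not show that the other genes stayed unchanged. The neuroendocrine list was shifted down with none of 13 members past the threshold (adjusted p = 0.0430, and adjusted p = 0.215 with an estimated correlation). Without scrambled, no doxycycline, replicate 2, 0 genes passed. Without replicate 1 of that group 5 passed, 4 up and 1 down, of which 1 belonged to the 3 genes. Without scrambled, doxycycline, replicate 1, or any 1 of the 4 hairpin doxycycline arrays, 1 passed.

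Doxycycline in the hairpin 1 subline lowered AKR1C3, MUC13, AKR1C4, MT1H (-1.92 ± 0.17, adjusted p = 4.19e-05) and A1CF most. The largest rises were TNFRSF19 (1.20 ± 0.21, adjusted p = 0.0133), ANXA1, a phospholipid-binding regulator of inflammation (1.20 ± 0.22, adjusted p = 0.0145), PNPLA7, a lysophospholipase (1.11), DUSP8 (1.09) and DSEL, of dermatan sulfate synthesis (1.05). In all 118 genes passed, 93 down and 25 up; with every array scaled to the same median the all-gene median was 0.16 and 90 passed, 50 down and 40 up. SPINK1 fell (-1.12 ± 0.19, adjusted p = 0.00924), a call lost without hairpin 1, no doxycycline, replicate 1 or without either hairpin 1 doxycycline array.

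By group, 7 of 25 intestinal and gastric genes fell, none rose and 18 did not pass (adjusted p = 5.42e-08; 9 fell and 1 rose adjusted over the list alone). Besides MUC13, A1CF, MYO1A, BAIAP2L2 and SPINK1 these were the cadherin CDH17 (-1.12 ± 0.24, at least 1.49-fold lower) and the clarin gene CLRN3, which was not above background with doxycycline. Of 25 glucuronidation and steroid genes 5 fell (adjusted p = 0.0177, and adjusted p = 0.0876 with an estimated correlation; 6 adjusted over the list alone). They were AKR1C2, AKR1C3, AKR1C4, UGT2B15 (at least 1.41-fold lower) and UGT2B17 (-1.42 ± 0.24, adjusted p = 0.00841, at least 2.03-fold lower). A second UGT2B17 probe changed by -0.67 and did not pass (adjusted p = 0.406). The amino acid and integrated stress response list was lower (adjusted p = 3.47e-04), with 2 of 45 members down, the hormone genes STC2 (-0.82) and GDF15 (-0.99), and 4 adjusted over the list alone. The cell cycle list (adjusted p = 0.00280) and the hypoxia list (adjusted p = 0.0280) were lower with no member past the threshold. Both calls were lost, with adjusted p = 0.0732 and adjusted p = 0.228 with an estimated correlation. Of androgen repressed genes 4 of 17 fell, UGT2B15, UGT2B17, the kinase inhibitor CAMK2N1 (-1.08) and DDC, which makes dopamine and serotonin (-1.33, at least 1.56-fold). The list did not pass (adjusted p = 0.113; median 0.06, mean -0.22). Of 39 androgen activated genes 1 fell, the elongation factor ELL2 (-1.12; list adjusted p = 0.160). The count of 118 fell to 62 and 54 without an array of the hairpin 1 group without doxycycline (replicates 1 and 2) and to 36 and 49 without a doxycycline array.

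By log2 value, doxycycline in the hairpin 2 subline lowered ELAVL1 most (-2.75 ± 0.20, adjusted p = 2.38e-05, at least 4.59-fold), followed by MUC13, AKR1C3, ASB9 and RNA28SN5, a copy of 28S ribosomal RNA (-1.94 ± 0.39, adjusted p = 0.0207). ELAVL1 and MUC13 ended below background, so their place in this order is uncertain. The level of RNA28SN5 without doxycycline was 1.98 higher than in the scrambled subline. A second RNA28SN5 probe (-1.23 and 1.30) passed neither test. The largest rises were 3 histone genes, H2BC21 (1.91 ± 0.19, adjusted p = 1.30e-04), H2AC6 (1.82 ± 0.22, adjusted p = 4.92e-04, detected on 1 of 2 arrays without doxycycline) and H2AC18 (1.43 ± 0.18, adjusted p = 7.04e-04), then PTBP2, a splicing regulator (1.32), and the gastric trefoil peptide gene TFF2 (1.25). In all 231 genes passed, 159 down and 72 up. SPINK1 changed by -0.47 ± 0.19 (adjusted p = 0.239) and did not pass.

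The interferon response list rose with hairpin 2 (3 of 35 members, 8 adjusted over the list alone; adjusted p = 2.78e-06; median 0.31): the RNA sensor IFIH1 (1.01), DTX3L (0.95, at least 1.76-fold higher) and HERC5 (0.60). The HERC5 call was lost whichever of the 12 arrays was left out. The adjusted p of the list was 0.113 with hairpin 1 and 0.289 in the scrambled subline. The cell cycle list was lower (2 of 72 fell, 2 adjusted over the list alone; adjusted p = 8.90e-07; median -0.21), with MELK, a mitotic kinase (-1.31), and cyclin E gene CCNE1 (-0.70) past the threshold. In the intestinal list 6 genes fell, TFF2 rose and 18 of 25 did not pass (adjusted p = 5.44e-04; 8 fell and 2 rose adjusted over the list alone). Beside MUC13, MYO1A, A1CF and BAIAP2L2 the falls were CDH17 (-1.06, at least 1.30-fold) and the brush-border protein VIL1 (-1.24, at least 1.41-fold). The same 5 glucuronidation and steroid genes as with hairpin 1 fell (adjusted p = 0.00132; 5 adjusted over the list alone). UGT2B15 was at least 1.53-fold lower and UGT2B17 (-1.21 ± 0.24) was detected on 1 of 2 doxycycline arrays, while a second UGT2B17 probe changed by -1.10 and did not pass (adjusted p = 0.0903). Another 4 lists passed and were lost with an estimated correlation. They were cholesterol synthesis (2 of 28 fell, MSMO1 at -0.75 and INSIG1 at -0.82; adjusted p = 0.0107, and adjusted p = 0.0641 with an estimated correlation) and hypoxia and glycolysis (1 of 30 fell, the mitophagy receptor BNIP3L with adjusted p = 0.0105; list 0.00413 and 0.163). So were androgen repressed genes (4 of 17 fell, the same genes as with hairpin 1; 0.0453 and 0.125) and p53 targets, which were higher with no member past the threshold (0.0409 and 0.110). Other probes of MSMO1 (-0.40 and 0.03) and INSIG1 (-0.64) did not pass. Of 39 androgen activated genes 3 rose, PLPP1 (0.77), the prostate membrane antigen FOLH1 (0.72) and LRIG1 (0.82; list adjusted p = 0.256). Other probes of PLPP1 (0.21 and 0.85) and LRIG1 (0.05) did not pass. Single members of other lists fell: the liver transcription factor ONECUT2 (-0.79), the luminal marker CD24 (-0.71) and the stress response factor DDIT3 (-0.72). The ONECUT2 call was kept in 1 of 12 fits without an array, and its 2 other probes changed by -0.51 and -0.49 and did not pass. The count of 231 fell to 58 and 64 without an array of the hairpin 2 group without doxycycline (replicates 1 and 2) and to 48 and 62 without a doxycycline array.

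The responses to the 2 hairpins differed for 23 genes, which asks which changes belong to 1 hairpin. ELAVL1 differed most (2.71 ± 0.29, adjusted p = 0.00234), and this call was kept whichever of the 12 arrays was left out. The zinc transporter SLC39A6 (1.92 ± 0.22, adjusted p = 0.00371), YRDC, of transfer RNA modification (1.62), the homeobox gene CUX1 (1.70) and ZNF789 (1.45) fell with hairpin 2 (-1.37 ± 0.16, -1.72 ± 0.16, -1.53 ± 0.20 and -1.11 ± 0.16) and did not pass with hairpin 1. Other probes of these genes did not pass for the difference. With hairpin 2 the other probes of YRDC (-0.79), CUX1 (-0.22) and ZNF789 (0.29 and -0.73) did not pass either, and that of SLC39A6 did (-1.36, adjusted p = 0.0467). The histone gene H2BC21 (-2.09 ± 0.27, adjusted p = 0.00918) rose with hairpin 2. The tetraspanin gene TSPAN4 (-1.60) and SMCO4 (-1.52) fell with hairpin 1 (-1.04 and -1.32). A second TSPAN4 probe fell with hairpin 1 (-0.96, adjusted p = 0.0342) and did not pass for the difference (-1.02). TMED5 (-1.49) and ZNF585A (-1.48) went opposite ways, and for ZNF585A a second probe differed by 0.39 and did not pass.

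In total 15 genes were higher and 8 lower with hairpin 1 than with hairpin 2 (19 and 2 when every array was scaled to the same median, where the all-gene median was 0.13). Of the 23, 18 passed with hairpin 2, 7 with hairpin 1 and 2 with both. HNF4G itself differed by 0.45 ± 0.25 (adjusted p = 0.541) and SPINK1 by -0.65 ± 0.26 (adjusted p = 0.373), and neither passed. The p53 list (adjusted p = 0.0214) and the interferon list (adjusted p = 0.0357) were lower with hairpin 1 than with hairpin 2, and both calls were lost, each with adjusted p = 0.150 with an estimated correlation. MELK (1.29) and BNIP3L (1.39) were the list members that passed, and second probes of MELK (0.58) and BNIP3L (1.23) did not. The count of 23 fell to 2 without hairpin 2, no doxycycline, replicate 2 or hairpin 2, doxycycline, replicate 2, and to between 3 and 15 without any other 1 of the 12 arrays.

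Differences between the sublines before induction were asked of the arrays without doxycycline. Both hairpin sublines had lower levels of steroid-metabolising genes than the scrambled subline. These were AKR1C2, which inactivates dihydrotestosterone (-2.31 ± 0.19, adjusted p = 8.53e-05 in the hairpin 1 subline and -2.00 ± 0.19, adjusted p = 1.75e-04 in the hairpin 2 subline). Lower too were the androgen-glucuronidating enzyme UGT2B17 (-2.00 ± 0.24 and -1.98 ± 0.24, while a second probe at -1.35 and -1.16 did not pass), AKR1C4 (-1.73 ± 0.19 and -1.86 ± 0.19) and UGT2B15 (-1.67 ± 0.18 and -1.60 ± 0.18). IL13RA2, a decoy receptor of interleukin 13, was below background in both (at least 2.07-fold and at least 2.30-fold lower). Higher in both were the phosphate transporter SLC20A2 (1.81 ± 0.17, adjusted p = 2.42e-04 and 1.85 ± 0.17, adjusted p = 1.75e-04), the prostate transporter SLC45A3 (1.36 ± 0.16, adjusted p = 6.18e-04 and 1.41 ± 0.16, adjusted p = 5.08e-04) and the Hedgehog receptor PTCH1 (at least 2.33-fold and at least 2.78-fold higher). CPLX3, which encodes a complexin of synaptic vesicle release, was above background in the hairpin 2 subline alone (2.39 ± 0.18, adjusted p = 4.33e-05, at least 3.29-fold higher). The transcription factor gene ELF5 was higher in both (1.28 and 1.13), and DRC10 in the hairpin 1 subline (1.21). A second ELF5 probe (0.81 and 0.57) did not pass.

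**Figure D4:**
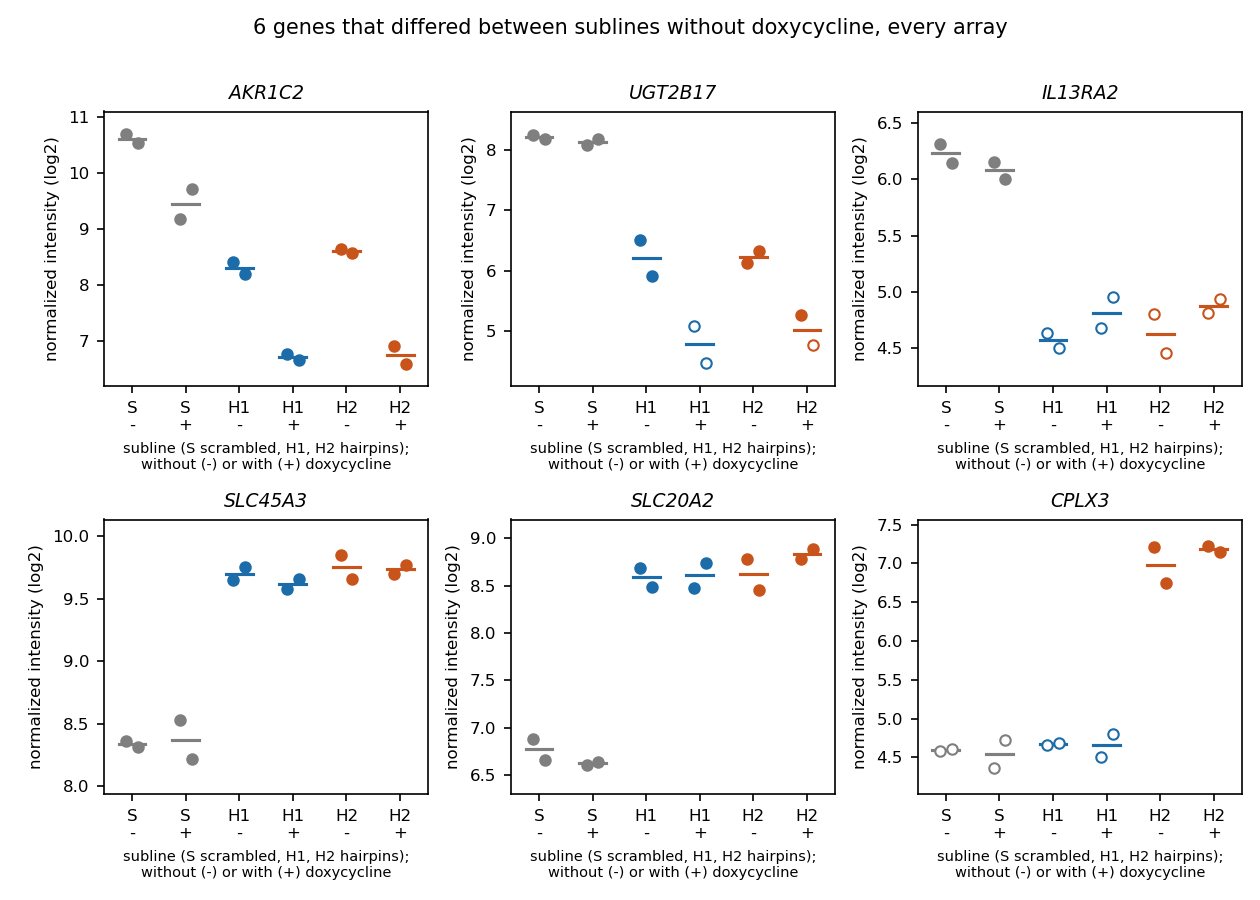
Normalized log2 intensity of 6 genes that differed from the scrambled subline (S) without doxycycline in the hairpin 1 (H1) or hairpin 2 (H2) subline, for every array. Points are arrays (2 per group), lines are group means and open points were not above background; AKR1C2 and UGT2B17 were lower and SLC45A3 and SLC20A2 higher in both hairpin sublines, and CPLX3 was above background in the hairpin 2 subline alone.

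In the hairpin 1 subline 70 genes differed (43 lower, 27 higher) and in the hairpin 2 subline 54 (35 lower, 19 higher). With every array scaled to the same median 49 were lower and 16 higher in the first and 33 lower and 47 higher in the second (all-gene median 0.13). Of 25 measured genes of glucuronidation and steroid metabolism, 7 were lower in each (adjusted p = 4.68e-09 and 3.84e-06; 9 adjusted over the list alone in each): AKR1C2, AKR1C4, UGT1A1, UGT2B10, UGT2B11, UGT2B15 and UGT2B17. The UGT2B genes are close paralogs whose probes can share signal, so how many of them differ is uncertain. Androgen activated genes were higher as a list (adjusted p = 2.99e-06 and 3.84e-06; medians 0.19 and 0.25) with SLC45A3 as the 1 of 39 members past the threshold (3 and 5 adjusted over the list alone). Androgen repressed genes were lower (adjusted p = 2.43e-04 and 0.00803, the second lost with adjusted p = 0.0868 with an estimated correlation), with UGT2B15 and UGT2B17 past the threshold. In the hairpin 2 subline the intestinal list was lower too (adjusted p = 0.0317, and adjusted p = 0.114 with an estimated correlation), with BAIAP2L2 past the threshold (-1.10), while with hairpin 1 it did not pass (adjusted p = 0.0638). Single members of other lists differed in both sublines, the interferon gene HERC5 upward (1.20 and 1.01) and the calcitonin gene CALCA (-1.37 and -1.29) downward, where 2 other CALCA probes did not pass. The 2 comparisons share the scrambled arrays. In both, 24 genes were lower and 12 higher, where independent lists would share 0.135 and 0.0460 and simulated unchanged groups 0.05 on average. The simulation called only 0.15 and 0.1 genes on average in the 2 comparisons, so it could share almost none. The covariance across genes was 0.0481 against 0.0185 in the simulation (r = 0.68 against 0.50). The controls were not split here either, so part of this overlap may come from them. A scrambled subline that itself differed from both hairpin sublines would give shared genes too. Leaving out scrambled, no doxycycline, replicate 2 left 13 and 14 genes. Leaving out an array of the hairpin subline itself left 31 and 17 for hairpin 1 and 20 and 12 for hairpin 2 (replicates 1 and 2).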

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

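The test against random lists was written beforehand; the tests of leaky hairpins, of weaker knockdown, of interferon, of doxycycline and of the dim array were chosen after the results were seen.

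The first kind of result given here is a difference between groups, tested as a difference of responses. The mean hairpin response differed from the scrambled response for 30 genes: AKR1C3 (log2 -2.57), ASB9 (-2.03), MUC13 (-1.96), NFASC (-1.79), ELAVL1 (-1.70), PON1 (-1.57), AKR1C4 (-1.56), SCARNA23 (-1.54), MT1F (-1.47), HNF4G (-1.45), A1CF (-1.45) and MT1H (-1.41) were lowest, and ANKRD52 (1.94), PLPPR2 (1.67), MAPRE3 (1.48) and GALNT1 (1.20) higher. Hairpin 1 differed from scrambled for 35 genes: AKR1C3 (-2.91), MT1H (-1.97), SCARNA23 (-1.86), MUC13 (-1.85), MT1F (-1.82), ANKRD52 (1.95), MAPRE3 (1.67), PLPPR2 (1.58), DUSP8 (1.58) and C21orf91 (1.44) most. Hairpin 2 differed for 36: ELAVL1 (-3.05), ASB9 (-2.35), AKR1C3 (-2.23), MUC13 (-2.07), NFASC (-2.04), ANKRD52 (1.93), H2AC6 (1.80), H2BC21 (1.76), PLPPR2 (1.75) and TMLHE (1.36) most. The hairpins differed from each other for 23: H2BC21 (-2.09), TSPAN4 (-1.60), SMCO4 (-1.52), TMED5 (-1.49) and ZNF585A (-1.48) were lowest with hairpin 1, ELAVL1 (2.71), SLC39A6 (1.92), CUX1 (1.70), YRDC (1.62) and ZNF789 (1.45) highest. Outside the named genes, 5 kept probes without a single gene name fell with both hairpins.

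The lower values in the scrambled subline with doxycycline (3 calls, and GALNT1 at adjusted p = 0.0513) give most of the rises against it. An effect of doxycycline on the cells was tested on the 3 genes called for their fall in the scrambled subline. The hairpin arrays enter this choice through the pooled spread and not through their own changes, and MAPRE3 and PLPPR2 kept the call in 4 of 12 fits without an array and ANKRD52 in 11. Such an effect would lower these genes in the hairpin sublines as well. The mean hairpin changes of ANKRD52, MAPRE3 and PLPPR2 were not below 0 (0.13 ± 0.13, 0.24 ± 0.12 and 0.32 ± 0.14), which argues against it for these 3 genes. They lay at least 7.10 standard errors above 0.5 of the scrambled change. Those standard errors leave out the error of the scrambled change, and choosing genes for their fall there overstates that fall, so the gap of 7.10 is too large. For GALNT1 an effect of doxycycline stays open. The same holds for AKR1C2, which was outside the test because it missed the threshold in the scrambled subline (-1.17 ± 0.19, adjusted p = 0.0513). AKR1C2 fell with both hairpins as well (-1.59 and -1.86), as such an effect would give, and did not pass against the scrambled response (-0.55 ± 0.23, adjusted p = 0.351). The dim scrambled doxycycline array, replicate 1, is argued against as the whole source too: without it 100.4% of the median scrambled change of the 4 genes was left, and 3 of the 4 passed against the scrambled response (PLPPR2 did not, adjusted p = 0.0604). In the scrambled subline itself 1 gene then passed, ANKRD52 (-1.81 ± 0.19 with it, -1.52 ± 0.19 without it). MAPRE3 (-1.24 ± 0.17 and -1.40 ± 0.20, adjusted p = 0.0556) and PLPPR2 (-1.34 ± 0.20 and -1.19 ± 0.24, adjusted p = 0.270) did not, as their standard errors grew and the fall of PLPPR2 shrank. The dim array was in the fit that chose the 4 genes, which favours genes whose 2 arrays agree, so the test of that array is weak. What set the scrambled subline apart stays open, since there is 1 subline per hairpin and no biological explanation was tested.

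The responses that differ between the hairpins could come from weaker knockdown with hairpin 1, which would not give changes with hairpin 1 that hairpin 2 lacks. Of the 23 genes 7 passed with hairpin 1 and lay further that way than with hairpin 2, and of 134 without background correction 40 did. With median scaling it was 1 of 21 (4.76%), no more than false calls could give. Without 1 scrambled array it was 4 of 15, 4 of 15, 4 of 11 and 4 of 11, and without 1 hairpin array 0 to 2 of 2 to 13. As the scalings disagree, weaker knockdown is left undecided. The difference of HNF4G itself had an adjusted p of 0.541, and its probe was below background with both hairpins. None of the 23 genes belongs to the interferon list. For the rise of that list with hairpin 2, a response that any induced hairpin would give is left undecided, because its difference between the hairpins had an adjusted p of 0.150 with an estimated correlation. Binding of hairpin 2 to other transcripts, ELAVL1 among them, stays open, since the hairpin sequences are not given in the sources used here, and so does drift, since there is 1 subline per hairpin.

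Genes that fell with both hairpins and were already lower in both hairpin sublines without doxycycline (AKR1C2, AKR1C4, BAIAP2L2, CLDN11, TMED6, UGT2B15 and UGT2B17) could reflect leaky hairpins. If these genes move in proportion to HNF4G, a leak of the size their shifts need would have shifted HNF4G by a log2 of -0.81 and -0.89. At the lowest share of the total fall among the 7 genes it would be -0.54 and -0.69. HNF4G differed by 0.01 and 0.21, a gap of 4.60 and 6.20 of its standard errors from -0.81 and -0.89. Under that assumption this argues against a leak for these 7 genes. They were chosen for being lower without doxycycline, which raises the expected shift, and those standard errors leave out the spread between them. Over all genes that fell with 1 hairpin, taken in the subline of the other, the hairpin 1 subline had no shift to explain (median -0.0046, 80 of 158 genes below 0, a gap of 0.0728 standard errors). In the hairpin 2 subline it was small (median -0.08, 52 of 92, a gap of 1.97), so this test decides nothing. Of random matched lists, 35.6% had a median as low as that of the 158 genes in the hairpin 1 subline and 0.4% as low as that of the 92 genes in the hairpin 2 subline, so a general shift is left undecided. Whether the 7 genes move in proportion to HNF4G was not tested. Of them AKR1C4, UGT2B15 and BAIAP2L2 passed in the main test, while AKR1C2 (-0.55 ± 0.23, adjusted p = 0.351) and UGT2B17 (-1.24 ± 0.29, adjusted p = 0.104) did not. For the other genes, and for these 7 if the assumption fails, differences between the sublines that arose before induction cannot be told apart from leaky hairpins here.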

How the results depend on the processing

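The alternatives were chosen before the results were seen and none was added. No call of a named gene reversed, and HNF4G stayed below 0 in every setting that could test it. Apart from the fits without 1 array, given below, its log2 change was -0.55 to -1.46 with hairpin 1 and -0.77 to -2.00 with hairpin 2. The filter on all 12 arrays leaves HNF4G out, and a slide block was not run. Of 146 calls of named genes, 135 were kept without background correction, 124 with median scaling, 126 without a filter, 144 with array weights, 142 with a trended and robust prior and 140 with every probe. Of those with a test, 96 of 126 were kept with only the arrays compared and 89 of 89 with the filter on all 12 arrays. With every probe, the probe with the smallest p was taken for each gene. A call could then be lost only through the wider adjustment or a changed prior, so the 140 do not show that other probes passed. A 1.5-fold minimum could remove no gene, because the smallest change that passed in any contrast (log2 0.592, hairpin 2) exceeded its log2 of 0.585. Array weights moved no count by over 1.5 times. Both arrays of a group received the same weight (0.883 for the scrambled doxycycline arrays), so this setting could not lower 1 array within its group. Counts below are in the order scrambled, hairpin 1, hairpin 2, mean hairpin against scrambled, hairpin 1 against scrambled, hairpin 2 against scrambled, hairpin 1 against hairpin 2, uninduced hairpin 1, uninduced hairpin 2 and both hairpins (3, 118, 231, 30, 35, 36, 23, 70, 54 and 47 as reported). No background correction gave 26, 245, 497, 125, 91, 177, 134, 111, 83 and 71, the series matrix values 26, 245, 498, 126, 91, 177, 134, 112, 82 and 72. A trended and robust prior gave 38, 267, 494, 131, 104, 191, 123, 128, 109 and 77; the cause was not tested. Median scaling gave 22, 118 and 56 for scrambled, hairpin 2 and the mean against scrambled. It matches the median of all 47323 probes and not that of the tested genes, whose median changes were then -0.16, 0.03 and 0.26. Other causes were not tested. The filter on all 12 arrays, which tests fewer genes, gave 18, 199, 385, 57, 57, 108 and 73 for the first 7. Only the arrays compared, which leaves fewer arrays to estimate the spread, gave 0 (scrambled; 3 with all 12 arrays by limma, with 1076 genes at an unadjusted p under 0.05), 49, 143, 12 and 23 for each hairpin against scrambled, 10 between hairpins, 17 for uninduced hairpin 1 and 28 for both. No filter gave 1 for scrambled, 28 for uninduced hairpin 2, a correlation of 0.19 between the hairpin responses (0.23 as reported) and 1 list in place of 3, and every probe gave 5 for scrambled and 14 between hairpins; the cause was not tested. With an estimated correlation 0 lists passed in the test against scrambled and with fry 9 (3 up, 6 down). With 2 arrays per group, probes near background limit the precision.

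The replicate number as a block gave 13 genes between the hairpins, and 141 of the 146 named calls were kept. The labels only number the replicates, and same-numbered arrays deviated together by a correlation of -0.03 to 0.07 over 15 pairs of groups, so no paired analysis is reported.

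Leaving out 1 array leaves its group with a lone array, which is assumed to vary like the other groups. The lowest and highest values were 0 and 5 for scrambled, 36 and 120 for hairpin 1, 48 and 214 for hairpin 2, 14 and 37 for the mean against scrambled, 2 and 24 for hairpin 1 against scrambled, 5 and 47 for hairpin 2 against scrambled, 2 and 15 between the hairpins, 13 and 76 for uninduced hairpin 1, 12 and 55 for uninduced hairpin 2, 17 and 42 for both hairpins, 0.166 and 0.237 for the correlation, and 0 and 4 for the lists. HNF4G changed by -0.43 to -0.05 in the scrambled subline, -1.53 to -1.40 with hairpin 1 (adjusted p 8.56e-04 to 0.0171) and -2.10 to -1.74 with hairpin 2 (9.57e-05 to 0.00244). Counts that moved by over 1.5 times follow, with replicates 1 and 2 of the array left out in that order. Correlations are given where they moved by at least their standard deviation over these same 12 fits. Without a scrambled array lacking doxycycline: scrambled 5 and 0, hairpin 1 against scrambled 21 and 9, between hairpins 15 and 15, and for replicate 2 alone 15 for the mean, 10 for hairpin 2 against scrambled, 13 and 14 for the uninduced sublines and 0 lists. Without a scrambled doxycycline array: hairpin 1 against scrambled 6 and 11, between hairpins 11 and 11, and for replicate 1 alone scrambled 1 and the mean 14. Without a hairpin 1 array lacking doxycycline: hairpin 1 62 and 54, against scrambled 9 and 17, between hairpins 5 and 13, uninduced 31 and 17, and for replicate 2 alone both 30 and the correlation 0.166. Without a hairpin 1 doxycycline array: scrambled 1 and 1, hairpin 1 36 and 49, against scrambled 4 and 2, between hairpins 3 and 3, both 25 and 26, and the correlation 0.181 for replicate 2. Without a hairpin 2 array lacking doxycycline: hairpin 2 58 and 64, against scrambled 14 and 10, between hairpins 7 and 2, uninduced 20 and 12, both 22 and 22, and the correlation 0.190 for replicate 1. Without a hairpin 2 doxycycline array: scrambled 1 and 1, hairpin 2 48 and 62, hairpin 1 against scrambled 20 and 20, hairpin 2 against scrambled 5 and 9, between hairpins 3 and 2, both 17 and 20, and the correlation 0.202 for replicate 2. Of 1752 named calls in these fits 1375 were kept.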

Other observations

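The families below were chosen after their values were seen, and their probes can share signal between near-identical members. Of 6 measured metallothionein genes, 5 fell with hairpin 1, 4 with hairpin 2 and 3 in the test against the scrambled response, and all 6 lay below 0 with both hairpins in every scaling, relative to an all-gene median that moved to 0.16 with hairpin 1 under median scaling. Under that scaling 4, 0 and 1 of them passed. Of 34 measured histone genes, 6 rose with hairpin 2 (H2BC21, H2AC6, H2AC18, H2AC19, H4C14 and H4C15) and 0 with hairpin 1 by limma, and 5 to 7 rose with hairpin 2 in the other scalings. With hairpin 2, 10 of the 34 lay below 0. Tested as differences, 1 of 34 passed between the hairpins, 2 for hairpin 2 against the scrambled response and 0 for the mean of both hairpins against it.

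Of the 41 genes that fell with both hairpins, 30 lay below 0 in the scrambled subline as well (median -0.16). Among 4405 kept probes without a single gene name, 13 passed with hairpin 1, 28 with hairpin 2 and 1 in the scrambled subline.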
